A study of Mus musculus with 6 samples.

How the data were processed

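RNA was sequenced from 6 libraries of sorted mouse thymocytes at the double-negative 1 (DN1) stage, which the labels describe as negative for lineage markers, TCRb, CD8a and CD25 and positive for CD44. The labels put 3 libraries in a WT group and 3 in a Tle134-deficient group and give an age range of 5 to 8 weeks. Tle134 is read here as Tle1, Tle3 and Tle4. Each library has its own title with a replicate number. Nothing in the labels says whether the 3 libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may be partly technical. Which antibodies made up the lineage mixture is not given in the sources used here.

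Per the submitters' processing notes, Trimmomatic 0.38, TopHat2 2.1.1 and featureCounts 2.0.1 were among the tools and mm9 was the genome build, with no role or order stated for them. The deposited tables hold FPKM (fragments per kilobase of transcript, scaled to the mapped total of the library) for each locus, with a lower and an upper bound, per the file headers. The column layout is that of a Cufflinks gene tracking table. The Cufflinks version, the annotation and the use of strand are not given in the sources used here. The loci without a gene symbol differ from table to table, as they do when each library is assembled on its own. Of the loci of a library, 67.5% to 87% carry no gene symbol, and the number of loci differs between libraries from 73915 to 184829. Between 1 and 9 loci with a symbol in each library exceed 10000 FPKM. FPKM is relative to the total of its own library, so a set of very abundant transcripts in 1 library lowers every other value there.

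Counts were not among the values used, so total reads per library are unknown. The width of the deposited interval gives an approximate depth. If it spans 2 SD of a fragment count on each side, the loci with a symbol hold 1.42e+06, 3.21e+06 and 3.24e+06 fragments in WT replicates 1 to 3 and 1.51e+06, 3.16e+06 and 4.34e+06 in the libraries labelled Tle134-deficient. The median locus above 0 then holds 26.9 to 121 fragments. WT replicate 1 and labelled-deficient replicate 1 are thus the shallowest, with the least precise values. Reads that fit several loci also widen such an interval, which would make these numbers too low. A value of exactly 0 can be a failed estimate: 45 genes are listed at 0 in 1 library and at 5 FPKM or more in all others. Rpl22l1, a ribosomal protein gene, is listed at 0 in labelled-deficient replicate 1 and at 34.2 to 139 FPKM in the other libraries. For genes listed at 0 the value of each library is given, with no mean and no fold against a group entirely at 0.

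Tables were joined on gene symbol. Symbols that share a locus in any library were joined into 1 unit and their FPKM added, which turned 24318 symbols into 23401 units, 427 of them holding 2 or more genes. H2-Ab1 and H2-Eb1 are such a unit. Cufflinks start positions count from 0 and were raised by 1. All coordinates are mm9. Where an assembled locus joins neighbours, a coordinate is that of the whole locus.

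The main test was chosen before the data were examined for count data, with limma on log2(value + 1) named as the substitute if the values were normalized, and the substitute was used. A gene was tested if it reached 1 FPKM in at least 3 libraries (11063 genes). The log2(FPKM + 1) values were fitted with limma 3.58.1 in R 4.3.3 with group as the only term, a mean-variance trend and a robust empirical Bayes step. P-values were adjusted by the Benjamini-Hochberg method and the threshold was 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. The tables were joined and the receptor regions read with Python 3.11.15 and pandas 2.3.3.

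Each of 22 gene lists was fixed before the data were examined. They cover the Groucho/Tle family, Tcf/Lef, Runx and partner factors, the Notch pathway, T-lineage and early progenitor genes, cell cycle genes, CDK inhibitors, p53 targets, the Bcl-2 family, Wnt/beta-catenin targets, immediate-early and heat shock genes, interferon response genes and sex-linked genes. The other lists hold markers of cells that the gate could contain: myeloid, dendritic, B, NK, innate lymphoid, gamma-delta and mature T, erythroid and megakaryocytic, mast and basophil, and stromal and endothelial cells. Lists were tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the lists. List members joined to a gene outside the list were not counted.

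Named genes follow a rule also fixed beforehand. It takes the Tle family, the 8 largest changes in each direction among genes past the threshold with no overlap between groups and a mean of at least 5 FPKM (written as CPM in the rule) in the higher group, up to 3 members per list by smallest adjusted p (1 for a list with no member past the threshold), and the sex-linked genes. Predicted gene models were left out of the largest changes. Other genes named were chosen after their values were seen. Some list members are not reported here by name, though they count in the list tests.

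On data simulated from the means and spread of these libraries (11063 genes, 5 runs, 200 changed genes each), the test recovered 27% of genes changed by 2 on the log2 scale and 83.6% of those changed by 4, and 4.33% of its calls were false. A list of 20 genes shifted by 1.5 was recovered and 0 of 20 unchanged lists passed the threshold. Genes were simulated independently of each other, and the changed genes were drawn only from those with higher means. The real lists had estimated inter-gene correlations of -0.0906 (Tle family) to 0.597 (cell cycle genes). The simulation therefore does not check list calls under such correlation, nor recovery among low genes.

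Alternatives fixed beforehand and run were median-ratio and upper quartile scaling, no filter, a filter at 5 FPKM, a non-robust fit, a threshold of 0.01, a pseudocount of 0.1, the replicate number as a block, each library left out in turn, and the other list tests. Quantile normalization, library weights, leaving out genes listed at 0 in any library and leaving out joined units were added after seeing the data. Tests that need counts were not used, since the values are FPKM. Fragments in loci without a symbol were used only for the immunoglobulin and T-cell receptor regions, each taken as the span between the neighbouring genes.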

Results

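The series compared the transcriptomes of WT and Tle134-deficient DN1 thymocytes, the CD44-positive, CD25-negative stage that holds the earliest progenitors of the thymus. The Groucho/Tle proteins are corepressors that bind Tcf/Lef, Runx and other transcription factors. Gene expression was measured as FPKM in 3 libraries per group, with an approximate depth of 1.42e+06 to 4.34e+06 fragments per library in annotated loci, as implied by the deposited intervals. Log2(FPKM + 1) values correlated between libraries with a Pearson coefficient of 0.774 to 0.788 within WT, 0.773 to 0.802 within the libraries labelled Tle134-deficient and 0.694 to 0.783 between groups. These are correlations across genes, which are not independent replicates. The first principal component held 30% of the variance and had negative scores in the WT libraries and positive scores in the libraries labelled Tle134-deficient. WT replicate 2 (-14.8) and labelled-deficient replicate 3 (13.2) lay closest on it. The second component held 25.4% and did not follow the labels, at -47.1 in WT replicate 3 and -59.1 in labelled-deficient replicate 3 against 2.3 to 61 in the others.

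The targeted genes were examined first, as a check of the genotype labels. Tle1 (chromosome 4, 71770979 to 71861938) measured 2.06 ± 1.35 FPKM in WT and 11.3 ± 0.185 FPKM in the libraries labelled Tle134-deficient (SD, n = 3 each). Tle3 (chromosome 9, 61220069 to 61266416) measured 28.5 ± 6.56 and 72.9 ± 12.6 FPKM, and Tle4 (chromosome 19, 14522464 to 14672673) measured 17.1 ± 2.25 and 26.9 ± 8.73 FPKM. Each mean was thus higher in the libraries labelled deficient, against the direction of the label. None passed the threshold over all genes: the log2 differences were 2.09 ± 0.47 (SE, limma adjusted p = 0.0954), 1.33 ± 0.41 (adjusted p = 0.234) and 0.58 ± 0.40 (adjusted p = 0.726). For Tle1 and Tle3, and not for Tle4, the lowest labelled-deficient value lay above the highest WT value. Separation of the groups in either direction was seen for 1685 of the 11063 genes tested (15.2%), where 10% would be reached by chance. FPKM over a whole locus includes reads outside any deleted exons, and no exon values were analysed here, so these values check the labels only in part. The group is therefore called the libraries labelled Tle134-deficient throughout.

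Among the other family members, Tle6 was listed at 0 in the 3 WT libraries and at 4.22, 1.35 and 4.09 FPKM in those labelled deficient (adjusted p = 0.122). Its locus overlaps the end of Tle2, so reads there cannot be assigned to 1 gene with certainty. Tle2 measured 5.17 ± 3.97 and 5.37 ± 2.54 FPKM, and Aes, which encodes a short family member without the repeat domain, measured 71.5 ± 26.1 and 71.0 ± 15.6 FPKM (SD, n = 3 each). Neither differed beyond the spread (adjusted p = 0.961 and 0.996). Of the 6 members, 0 passed the threshold over all genes and 3 (Tle1, Tle6 and Tle3) were higher when adjusted over the list alone. The family as a list was higher (median log2 difference 0.96, camera adjusted p = 0.00269; adjusted p = 0.177 with an estimated correlation).

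**Figure D1:**
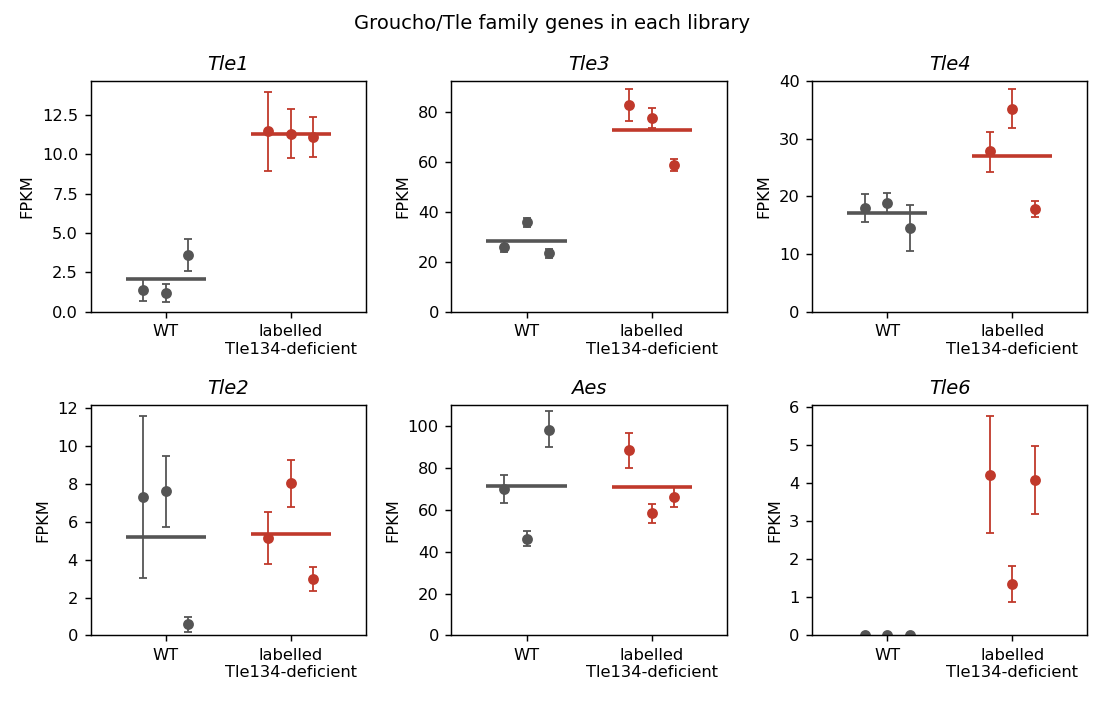
FPKM of the 6 Groucho/Tle family genes in each library, WT in grey and libraries labelled Tle134-deficient in red. Points are libraries with the deposited interval and horizontal lines are group means (omitted for Tle6, listed at 0 in WT). The labelled-deficient values of Tle1 (11.1 to 11.5 FPKM) and Tle3 (58.6 to 82.6 FPKM) lie above the WT values, and those of Tle4, Tle2 and Aes overlap them.

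Which genes differed between the WT libraries and those labelled Tle134-deficient was the main comparison. Cd22, Cd74 and the MHC class II genes H2-Ab1/H2-Eb1 and H2-Aa rose in the libraries labelled Tle134-deficient, and Dntt and Tox fell. These directions follow the labels, which the targeted genes did not bear out. Of 11063 genes tested, 71 were higher and 12 lower (limma, adjusted p under 0.05), and all 83 changed by more than 2-fold. The MHC class II unit H2-Ab1/H2-Eb1 (chromosome 17, 34400172 to 34453619) went from 78.8 ± 72.7 to 1330 ± 403 FPKM, a log2 difference of 4.39 ± 0.68 (SE, adjusted p = 0.0279). Cd74 (chromosome 18, 60963494 to 60972306), the class II invariant chain, went from 135 ± 112 to 2140 ± 511 FPKM. Cd22 (chromosome 7, 31650423 to 31665361), an inhibitory coreceptor of B cells, went from 2.02 ± 0.69 to 55.6 ± 13.3 FPKM and had the smallest adjusted p of all genes (log2 difference 4.22 ± 0.41, adjusted p = 0.0154). The other largest rises among genes past the threshold were H2-Aa (whose span lies within that of the H2-Ab1/H2-Eb1 unit), Nxpe4, Fcmr (the IgM Fc receptor gene), Cxcr5 and Rgs13. Cxcr5, which encodes a chemokine receptor of follicular lymphocytes, was at 1.99, 0 and 6.04 FPKM in WT and at 63.8, 47.7 and 35.4 FPKM in the libraries labelled deficient. Rgs13, a regulator of G-protein signalling known from germinal centre B cells and mast cells, was listed at 0 in WT and at 10.4, 44.9 and 11.5 FPKM.

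Dntt (chromosome 19, 41103765 to 41134015) showed the largest fall among genes past the threshold. It encodes terminal deoxynucleotidyl transferase, which adds nucleotides to rearranging receptor genes in lymphoid progenitors. It fell from 186 ± 83.8 to 7.95 ± 7.15 FPKM (log2 difference -4.60 ± 0.65, adjusted p = 0.0279). Tox (chromosome 4, 6614296 to 6918812), a nuclear factor of T-cell and innate lymphoid development, fell from 35.6 ± 6.89 to 4 ± 2.22 FPKM (-2.98 ± 0.47, adjusted p = 0.0279). Ccl11, an eosinophil chemokine, fell from 27.6 ± 18.8 to 1.15 ± 0.847 FPKM and Egfl7, a gene of endothelial and some progenitor cells, from 19.0 ± 3.22 to 1.99 ± 2.17 FPKM (SD, n = 3 each). Serpinf1 was at 24.2, 16.2 and 30.6 FPKM in WT and at 0, 1.59 and 3.50 FPKM in the libraries labelled deficient. Ctla2a was at 12.6, 27.8 and 35.9 FPKM in WT against 0, 0.87 and 4.04 FPKM, and its near-identical neighbour Ctla2b at 5.48, 7.69 and 10.2 against 0, 0 and 0.611 FPKM, so reads may be split between the 2. Rab26os, an antisense transcript whose reads cannot be told from those of its partner without strand, was at 8.59, 11.2 and 33.8 FPKM in WT against 0, 0 and 1.79 FPKM.

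Without WT replicate 1, labelled-deficient replicate 1 or labelled-deficient replicate 2, limma called 0 genes (877, 951 and 956 genes at an unadjusted p under 0.05, against 1109 with all libraries), and 2 higher and 2 lower without WT replicate 2, 56 and 2 without WT replicate 3, and 34 and 11 without labelled-deficient replicate 3. Without a filter on low values 0 of 18942 genes passed (1181 at an unadjusted p under 0.05).

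B-lineage genes formed the list with the strongest shift, upward in the libraries labelled deficient. Of 23 members tested, 12 rose, 1 fell (Dntt, which early T and early B cells share) and 10 did not pass; adjusted over the list alone, 18 were higher and 1 lower. The median log2 difference was 3.13 (camera adjusted p = 1.49e-21; adjusted p = 0.177 with an estimated correlation). The members that rose include both signalling chains of the B-cell receptor, Cd79a (18.1 ± 17.7 to 219 ± 63.8 FPKM) and Cd79b (12.9 ± 8.89 to 141 ± 53.1 FPKM), the surface protein Ms4a1 (7.93 ± 8.09 to 101 ± 23.4 FPKM), and Fcer2a, the low-affinity IgE receptor of mature B cells (log2 difference 4.01, adjusted p = 0.0279). Among genes of early B-cell stages, Igll1, higher over the list alone, was at 0, 0.392 and 0 FPKM in WT and at 1.58, 1.29 and 1.42 FPKM in the libraries labelled deficient. Vpreb1 overlapped between the groups, at 4.44, 0 and 0 FPKM in WT against 3, 1.15 and 0 FPKM. In WT the B-lineage genes were also present, and 15 of the 23 members reached 1 FPKM in each WT library, with the highest mean in WT replicate 3. The 15 include Dntt, and the count is not particular to this list, as 20 of 21 T-lineage and 19 of 21 innate lymphoid members reached that level.

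Dendritic cell genes moved with them. Of 18 members, 5 rose (the H2-Ab1/H2-Eb1 unit, H2-Aa, Cd74, Ciita and Spib), 0 fell and 13 did not pass; adjusted over the list alone, 9 were higher (median log2 difference 1.33, camera adjusted p = 1.55e-09; adjusted p = 0.177 with an estimated correlation). All 5 are also genes of B cells: Ciita, the class II transactivator, went from 1.66, 4.34 and 4.38 FPKM in WT to 55.9, 66.9 and 29.1 FPKM, and Spib, an Ets factor of B cells and plasmacytoid dendritic cells, from 1.53, 1.94 and 4.17 to 38.6, 29.1 and 21 FPKM. Some members more specific to dendritic cells did not pass, among them Itgax (adjusted p = 0.986), Siglech (adjusted p = 0.984) and Zbtb46 (adjusted p = 0.952). Higher over the list alone, though not over all genes, were Cd83, Irf8, Tcf4 and Ccr7 (log2 differences 3.98, 2, 1.61 and 1.67). Of the 18 differences, 16 were above 0 and 2 below.

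T-lineage genes leaned the other way. Of 21 members, 1 fell (Tox), 0 rose and 20 did not pass; adjusted over the list alone, 2 were lower (Tox and Cd247). The median log2 difference was -0.70, with 18 of 21 differences below 0 (camera adjusted p = 3.07e-06; adjusted p = 0.557 with an estimated correlation). It was -0.31 without labelled-deficient replicate 3, -0.48 without WT replicate 3, -1.07 without WT replicate 2 and -1.22 without labelled-deficient replicate 1. Relative to the WT mean, the list mean of labelled-deficient replicate 1 (-0.20) lay above that of WT replicate 2 (-0.58). Labelled-deficient replicate 3, the lowest in T-lineage genes (-1.56), was also the highest in monocyte, macrophage and neutrophil genes, with a list mean of 2.2 against -0.15 and -0.29 in replicates 1 and 2 and -0.70, -0.36 and 1.07 in WT. Cd247, the zeta chain of the T-cell receptor complex, was at 104, 39.7 and 106 FPKM in WT and at 22.6, 12.1 and 11.7 FPKM in the libraries labelled deficient (adjusted p = 0.0897). Several T-cell genes were as high in labelled-deficient replicate 1 as in WT and low in replicate 3: Tcf7 was at 239, 121 and 39.5 FPKM in the 3 labelled-deficient libraries against 229, 164 and 213 FPKM in WT, and Bcl11b at 43.7, 9.13 and 3.49 against 36.4, 18.4 and 20.8 FPKM.

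**Figure D2:**
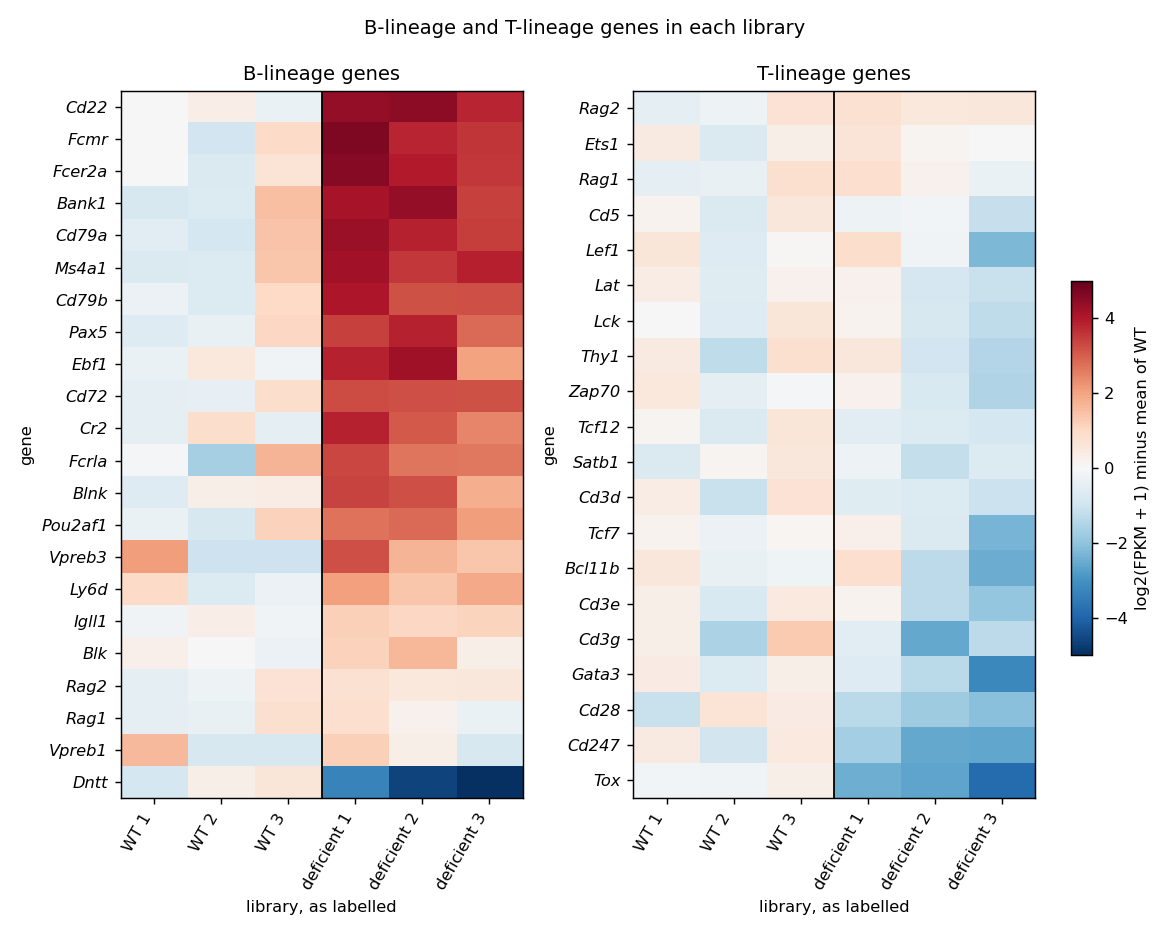
Log2(FPKM + 1) minus the WT mean for 22 of the 23 tested members of the B-lineage list (left) and 20 of the 21 of the T-lineage list (right), with genes in rows and libraries in columns as labelled. Red is above and blue below the WT mean; most B-lineage genes are red in the 3 labelled-deficient libraries, Dntt is blue there, and several T-lineage genes such as Tcf7, Bcl11b and Gata3 are bluest in labelled-deficient replicate 3.

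Notch pathway and early progenitor genes showed no shift past the threshold as lists. None of 8 Notch pathway members passed over all genes, and adjusted over the list alone 1 was higher and 2 lower (camera adjusted p = 0.334). The higher one was Dtx1, an E3 ligase induced by Notch that is also expressed in B cells, at 1.85, 2.5 and 1.09 FPKM in WT and 27.5, 13.8 and 9.18 FPKM in the libraries labelled deficient (adjusted p = 0.0626). The lower pair was Notch3 (4.32 ± 0.401 and 0.957 ± 0.611 FPKM, adjusted p = 0.261) and Notch1 (36.3 ± 28.2 and 10.2 ± 4.02 FPKM, adjusted p = 0.332). Of 17 early progenitor genes none passed over all genes, and Lmo2 was higher and Mycn lower over the list alone (camera adjusted p = 0.334). Lmo2, a transcription cofactor of progenitors, measured 14.7 ± 7.18 and 53.9 ± 22.1 FPKM (adjusted p = 0.166). Mycn measured 14.4 ± 2.77 and 4.13 ± 2.18 FPKM (limma adjusted p = 0.194). Of the 17 differences, 7 were above 0 and 10 below. Of 13 Tcf/Lef, Runx and partner genes 0 passed (camera adjusted p = 0.303), with Runx1 at the smallest adjusted p of the list (0.718).

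Among markers of other cells, 1 of 19 gamma-delta and mature T-cell genes fell and 0 rose; adjusted over the list alone 5 were higher and 3 lower, and the list as a whole showed no shift past the threshold (camera adjusted p = 0.62). The member that fell was 5830411N06Rik, a scavenger receptor gene related to the gamma-delta T-cell marker Cd163l1. It was at 70.3, 74.2 and 57.4 FPKM in WT and at 14.5, 8.14 and 3.02 FPKM in the libraries labelled deficient (limma adjusted p = 0.0353). Cd163l1 itself did not differ beyond the spread, at 24.7, 7.49 and 7.3 FPKM in WT against 29.2, 9.45 and 7.61 FPKM (limma adjusted p = 0.975). Sox13, a gamma-delta lineage factor, was at 91.1, 30.8 and 39.0 against 12.3, 7.34 and 1.66 FPKM (adjusted p = 0.0906), and Klf2, a factor of circulating lymphocytes, at 29.1, 37.0 and 25.0 against 178, 189 and 81.4 FPKM (adjusted p = 0.0897). Of 12 stromal and endothelial genes, Pdgfrb fell (14.98, 22.15 and 14.81 against 2.384, 2.397 and 3.629 FPKM, adjusted p = 0.0469) and the others did not pass, among them Pdgfra (adjusted p = 0.196) and Col1a2 (adjusted p = 0.293); adjusted over the list alone 2 were lower (camera adjusted p = 0.0695). The mast cell and basophil list was lower (median log2 difference -1.10, camera adjusted p = 8.64e-05; adjusted p = 0.557 with an estimated correlation) with 0 of 12 members past the threshold over all genes and 4 lower adjusted over the list alone. Relative to the WT mean, the list mean was -2.54 and -2 in labelled-deficient replicates 1 and 2, but 0.18 in replicate 3, against 0.06, -0.89 and 0.83 in WT. The median was -1.90 without labelled-deficient replicate 3 and -0.69 without replicate 1. Tpsb2, a mast cell tryptase, was at 5.82, 3.66 and 17.5 FPKM in WT and listed at 0 in the 3 libraries labelled deficient (adjusted p = 0.05, not past the threshold).

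The remaining lists had 0 members past the threshold over all genes. Interferon response genes were higher (22 members, 1 over the list alone, Oas1a; median log2 difference 0.43, camera adjusted p = 0.0245; adjusted p = 0.557 with an estimated correlation) and cell cycle genes lower (24 members, 0 over the list alone, Cdc20 first; median -0.35, camera adjusted p = 0.039; adjusted p = 0.813 with an estimated correlation). The cell cycle list mean was above 2 of the WT libraries in labelled-deficient replicate 3 (0.41 against -0.20, -0.31 and 0.51). Its median was -0.76 without that library and -0.53 without WT replicate 2, and the call was lost without labelled-deficient replicate 1 (median -0.23, adjusted p = 0.17), labelled-deficient replicate 2 (-0.08, 0.324) or WT replicate 3 (-0.10, 0.223). The interferon call was lost without labelled-deficient replicate 1 (median 0.26, adjusted p = 0.187), and its median was 0.26 without replicate 3 and 0.65 without replicate 2. Camera found no shift past the threshold of the NK and cytotoxic list (adjusted p = 0.0695, 3 of 10 members lower over the list alone, Fasl first), of the innate lymphoid list (adjusted p = 0.334, 2 of 21 higher over the list alone, Ccr6 first), or of the Bcl-2 family (adjusted p = 0.121, Bcl2a1b, whose reads may be split with near-identical copies, higher over the list alone). The same held for monocyte, macrophage and neutrophil genes (adjusted p = 0.112; Ctss had the smallest p), Wnt/beta-catenin targets (0.426; Apcdd1), immediate-early and heat shock genes (0.568; Hspa1a), erythroid and megakaryocyte genes (0.688; Car2), CDK inhibitors (0.697; Cdkn2a) and p53 targets (0.963; Bbc3), none of which had a member past the threshold over the list alone. For CDK inhibitors the median log2 difference was -0.16, while the mean was 0.09 and camera pointed up. For p53 targets the median was -0.11 and camera pointed down, while the mean was 0.1 and fry pointed up. Of the sex-linked genes, Xist was at 34.7 to 81.0 FPKM in the 6 libraries and the Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty were listed at 0 in all of them.

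**Figure D3:**
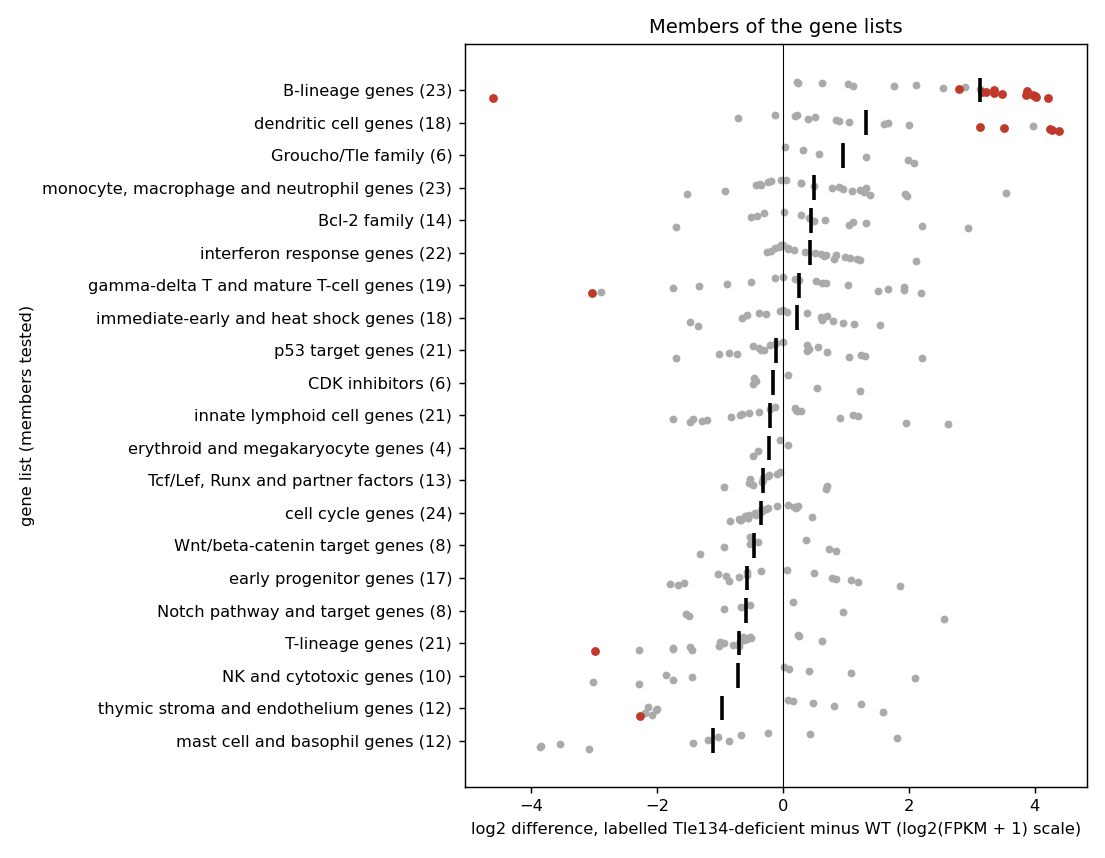
Log2 difference (libraries labelled Tle134-deficient minus WT, log2(FPKM + 1) scale) of each tested member of 21 gene lists, with the number of members tested in brackets. Red points passed the threshold over all genes, grey points did not, and black bars are list medians, from 3.13 for B-lineage genes to -1.10 for mast cell and basophil genes.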

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

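The tests of early B-cell genes and of other scalings were chosen after the result was seen. The immunoglobulin heavy and kappa test and the count of splits were chosen before.

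Loci without a gene symbol, which the comparisons above do not use, held a larger summed share of fragments in the immunoglobulin lambda region (chromosome 16, 18812066 to 19285886, mm9) in each library labelled Tle134-deficient than in any WT library. The lowest labelled-deficient share was 1.44 times the highest WT share. Per 1000000 fragments in annotated loci, the region held 157, 444 and 631 fragments in WT and 1314, 1626 and 908 in the libraries labelled deficient. The loci were assembled apart in each library and covered 6.42, 32 and 145 kb in WT against 209, 208 and 219 kb, so the sum also moves with how much was assembled. Per covered kb the share was 24.4, 13.9 and 4.36 in WT against 6.29, 7.82 and 4.14, which is not higher in the libraries labelled deficient. The lambda region was 1 of 7 readouts computed, and the summed shares of the heavy and kappa regions overlapped between the groups. Per covered kb the heavy region went the other way from lambda, at 10.01, 9.49 and 11.2 in WT against 93.7, 35.1 and 23.7, and the kappa region overlapped, at 74.6, 7.69 and 89.1 against 59.9, 21.9 and 3.86. These shares per covered kb were computed after the sums were seen.

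B-lineage genes were higher in the libraries labelled Tle134-deficient, and 3 explanations were weighed. Pro-B or pre-B cells were argued against only weakly. The 5 early B-cell genes had a median log2 difference 3.04 below that of the 18 other members (-3.04, SD of the others 0.86). Of these 5, Rag1 and Rag2 are also in the T-lineage list and early T cells share Dntt, which weakens the test. The rest, Igll1 and Vpreb1, differed by 1.12 ± 0.42 and 0.22 ± 0.77 (SE), below the median of 3.29 of the other members. Vpreb1 thus did not differ beyond its error. Both genes lie near the floor, where the log2(FPKM + 1) scale understates change, which weakens the test further. Scaling was argued against, since the list median stayed at 3.02 or more over 3 other scalings. Mature B cells in the sorted fraction are a candidate explanation that was not settled: the prediction made before the result, a larger heavy plus kappa share in each labelled-deficient library, was missed, with a ratio of the lowest labelled-deficient to the highest WT share of 0.685 (WT 3634, 3843 and 4309 per 1000000 over 213, 440 and 220 kb; labelled deficient 6029, 5850 and 2952 over 77.9, 218 and 461 kb, or 17.1, 8.74 and 19.6 against 77.4, 26.8 and 6.41 per covered kb). As written, the prediction counted a ratio of at most 1 against mature B cells. The explanation was kept open for reasons found only after that miss. First, the miss of 1360 per 1000000 is smaller than the SD of the labelled-deficient libraries (1730). Replicate 3, the library behind the miss, itself widens that SD, so this is a weak yardstick. Second, the regions may also hold transcripts of antibody-secreting cells, for which Jchain was the only gene used. Jchain was at 35.9, 25.7 and 240 FPKM in WT and at 0, 0.148 and 9.72 FPKM in the others. Open therefore remain B cells that passed a lineage gate whose antibodies are not given (Cd79a reached 161 to 287 FPKM; 15 of the 23 list members reach 1 FPKM in each WT library and 3 are in another list), B-lineage genes raised in the sorted cells by the genotype, and labels exchanged between whole groups.

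The count of called genes was compared with other splits of the libraries. The real grouping called 83 genes and the highest of the 9 others called 1. With 10 splits of 6 libraries, 1 of which reached the real count, the share can never be under 0.1, so the splits are too few for a test at 0.05. At an unadjusted p under 0.05 the real grouping gave 1109 genes, and the split that sets WT replicates 1 and 2 and labelled-deficient replicate 2 against the others gave 1106.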

How the results depend on the processing

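Quantile normalization, library weights, and leaving out genes listed at 0 or joined units were chosen after seeing the data. The counts of genes higher (71) and lower (12) became 0 and 0 without a filter on low values (1181 genes at an unadjusted p under 0.05) and 0 and 0 at a threshold of 0.01. Genes higher and lower numbered 64 and 6 with the non-robust fit, 50 and 3 with a pseudocount of 0.1, and 105 and 20 with library weights. The cause was not tested. In the 6 other settings on all libraries without the block, 60 to 81 genes were higher and 13 to 16 lower. Leaving out 1 library gave 0 to 56 genes higher and 0 to 11 lower, with fewer libraries in each fit. The 83 genes, selected by adjusted p and all with differences of at least 2.1 on the log2 scale, kept their sign in each setting that tested them (69 to 83 tested). After such a selection this says little on stability. Upper quartile scaling moved the median log2 difference of all genes from 0.036 to -0.086, and the other scalings on all libraries moved it less.

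With the replicate number as a block 1 gene was higher and 1 lower. Libraries with the same number correlated in their deviations from the group means by 0.08, 0.18 and 0.17, so the numbers were not taken to pair them, although 6 of 6 libraries correlated best with their own number, a hint from the data and not from the design. No list changed its side of the threshold under the block.

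With an estimated correlation the camera calls were lost for the B-lineage, dendritic and Tle family lists (adjusted p = 0.177 each), the T-lineage, mast cell and interferon lists (0.557 each) and the cell cycle list (0.813). By fry they were lost for the T-lineage and interferon lists (0.404), mast cell (0.408) and cell cycle (0.801) lists. Leaving out 1 library moved the camera adjusted p from 0.000314 to 0.324 for cell cycle genes, 0.00704 to 0.187 for interferon genes, 0.0413 to 0.971 for early progenitor genes, 0.0262 to 0.294 for NK genes, 0.00598 to 0.798 for monocyte, macrophage and neutrophil genes and 0.0153 to 0.508 for stromal genes. The B-lineage, dendritic, T-lineage, mast cell and Tle family lists stayed under 0.05 in each of these 6 fits, under both other scalings tried on lists and under the block. Tle1, Tle3 and Tle4 kept their sign and stayed above 0.05 in every setting tried (adjusted p 0.0511 to 0.277, 0.148 to 0.543 and 0.513 to 0.947). Of the other named genes, the 21 past the threshold had 371 values under an alternative, of which 195 stayed past it and 176 did not. The 25 not past it had 437, of which 14 passed it and 11, of 4 genes, turned their sign. Aes (0.03) turned to -0.03, -0.11 and -0.11 by median-ratio, upper quartile and quantile scaling (adjusted p = 0.991, 0.956 and 0.947), and Xist (0.09) to -0.05 and -0.08 by upper quartile and quantile scaling (0.981 and 0.967). Aes also turned without WT replicate 2 or labelled-deficient replicate 1, Xist without WT replicate 1 or labelled-deficient replicate 3, Tle2 without WT replicate 3 and Car2 without labelled-deficient replicate 2 (adjusted p over the libraries left out 0.874 to 1, 0.892 to 1, 0.815 to 1 and 0.307 to 1).

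The direction of the list test turned in 14 values of 8 lists, none past the threshold before or after. These were p53 targets by fry (adjusted p = 0.814), immediate-early and heat shock genes by quantile normalization (0.953), and, with 1 library left out, those 2 lists (0.74 to 0.974 and 0.0721 to 0.894), CDK inhibitors (0.5 to 0.864), innate lymphoid (0.0565 to 0.974), gamma-delta and mature T-cell (0.141 to 0.954), erythroid and megakaryocyte (0.133 to 0.995), early progenitor, and monocyte, macrophage and neutrophil genes (ranges above). The cause was not tested.

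The planned tests that need counts were not run. Scaling by library size alone and a filter at 1 FPKM were not run apart, as FPKM already has that scaling and the filter is the main one. Depth limits genes near 1 FPKM most in WT replicate 1 and labelled-deficient replicate 1 (1.42e+06 and 1.51e+06 implied fragments).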

Other observations

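The tests of scaling, of 1 wrong label (a second measure being added after the first was known) and of dilution were chosen after the results were seen; the relation of Tle1 and Tle3 to B-lineage RNA was set before.

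Labelled-deficient replicate 3 had values above those of the other libraries in some granulocyte and basophil genes, picked after their values were seen, and not in others: S100a8 was at 22.93 FPKM there and at 30.85 in WT replicate 3, Mcpt8 at 16.3 and 24.7, and the mean of the mast cell and basophil list lay at 0.18 and 0.83 relative to the WT mean. Prg2, which encodes the eosinophil major basic protein, was at 1240 FPKM there and at 0 to 25.5 FPKM in the 5 other libraries. Ngp, a neutrophil granule gene, was at 340 FPKM against 0 to 1.82, S100a9 at 333 against 0 to 27.0 and the basophil protease Prss34 at 139 against 0.205 to 9.96. Mpo and Elane, genes of early granulocyte granules, were at 589 and 266 FPKM there, and also at 84.0 to 257 and 19.3 to 142 FPKM in WT. Without this library 34 genes were higher and 11 lower, and the B-lineage list kept a median log2 difference of 3.24.

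Connective tissue mast cell proteases were seen in WT. Cma1 was at 9.59, 1.63 and 55.2 FPKM and Mcpt4 at 21.8, 1.40 and 57.0 FPKM, while in the libraries labelled deficient Cma1 was listed at 0 and Mcpt4 at 0, 0 and 0.0921 FPKM. Cpa3, a mast cell and basophil carboxypeptidase, was at 54.4, 35.0 and 110 FPKM against 0.992, 0.622 and 21.5 FPKM (limma adjusted p = 0.109). In loci without a symbol, which were assembled apart in each library, the T-cell receptor gamma region held 1627, 711 and 839 fragments per 1000000 in WT and 444, 504 and 224 in the libraries labelled deficient (21.5, 20.2 and 29.4 against 22.2, 8.15 and 11.9 per covered kb, over 75.8, 35.2 and 28.6 against 20, 61.9 and 18.9 kb). The beta region held 1753, 1733 and 1483 against 1308, 648 and 935 (70.8, 63.1 and 45.3 against 75.1, 33.3 and 40.7 per covered kb, over 24.8, 27.5 and 32.8 against 17.4, 19.4 and 23 kb). Summed shares of the alpha and delta region were 1531, 1211 and 765 against 756, 835 and 376, with overlap between the groups.

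Tle1 and Tle3 were higher in the libraries labelled Tle134-deficient. Neither passed the threshold over all genes (limma adjusted p = 0.0954 and 0.234), so chance stays open as well. Scaling was argued against, as the lowest of their log2 differences over 3 other scalings was 1.19. A single wrong label would place a library among those of the other group. No library lay so in Tle1, Tle3, Cd22 or the mean of the B-lineage list, but this cannot decide on a wrong label. The lowest labelled-deficient value was at least 1.64 times the highest WT value in Tle1, Tle3 and Cd22. The lowest labelled-deficient mean of the B-lineage list, taken up afterwards, lay 1.42 above the highest WT mean on the log2 scale (SD 0.41 in WT and 0.46 in the others). Both tests used genes already seen to separate the groups, so their outcome was given in advance, and Tle4 overlapped between the groups. A single wrong label therefore stays open. RNA of B cells, which may carry its own Tle1 and Tle3, stayed undecided: the correlation with the mean of the B-lineage list, over the 6 libraries as deviations from the group means, was 0.69 for Tle1 (exact permutation p = 0.0278, adjusted 0.0556; Spearman 0.83, p = 0.0278, adjusted 0.0556; 0.18 without the 2 libraries farthest from the median) and 0.02 for Tle3 (exact permutation p = 0.972, adjusted 0.972; Spearman 0.09, p = 0.917, adjusted 0.917; 0.30 without those 2). These were the 2 relations computed, 0.0278 is the smallest p that 36 permutations can give, the Tle1 relation rests on those 2 libraries, and transcripts that remain or rise when exons are deleted and labels exchanged between whole groups stay open as untested.

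Dntt and Tox were lower in the libraries labelled Tle134-deficient. Dilution of all other cells by B cells would lower the remaining T-lineage genes as much. The median of the 20 other T-lineage genes lay 2.28 above Tox on the log2 scale (-0.70 against -2.98, SD of the members 0.71), so as a set they fell less. Since Tox had the largest fall of the list, some gap was given in advance. Dntt, which is not in that list but was also picked for its fall, differed by -4.60. Both lie beyond the -0.70 of the set by more than its SD of 0.71. This argues against dilution as the only cause of the 2 falls. Whether dilution accounts for a part of them is not decided. A fall of Dntt and Tox within the sorted cells, or a lower share of the cells that express them, may account for the values and stays open. Dilution as a part of the falls and the genotype itself stay open as well.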
